A study of Mus musculus with 2 samples.

How the data were processed

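H3K27me3 ChIP-seq was measured in lung of mouse embryos at 15.5 days, in 2 biological replicates, each made from a separate pool of embryos per the labels. Fragments were selected at 300 to 500 bp per the labels. The labels name more than 1 model of Illumina HiSeq for replicate 1 and no instrument for replicate 2. The files analysed were 4 peak lists in narrowPeak format on the mm10 assembly, named by the deposited descriptions. Per those deposited descriptions the list of replicate 1 was made from its filtered alignments and 1 control file, that of replicate 2 from its own alignments and 2 control files, and a pooled list from the alignments of both with 2 control files. The list of replicated peaks was derived from the other 3 lists. The aligner, the peak caller, their versions and the overlap rule for replicated peaks are not given in the sources used here. For each peak the authors deposited a signal value, whose scale is not stated and which was used to rank or filter peaks within a list, except that log2 ratios between the replicates were compared between X and autosomes, and −log10 of a p-value and of a q-value. These scores are the authors' own. Every list began just above a −log10 p of 2, and 12.7% of the peaks of replicate 1, 16.7% of those of replicate 2 and 1.0% of replicated peaks had a q-value above 0.05. Because the control files differ in number between the replicates and depth is unknown, list lengths cannot be compared as amounts of the mark.

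Peaks were placed on the GRCm38 reference, the assembly of mm10, with the GENCODE M21 annotation. All peaks lay within the chromosome lengths. Chromosomes 1 to 19 and X were used, which left out 1 peak of replicate 1 on an unplaced scaffold. The background was 21728 protein-coding genes, 1 per symbol, from 21755 records. Another 183 genes on chromosome Y were left out, since no list had a peak there. The TSS was the 5′ end of the gene record, the promoter was TSS ± 1 kb, and a gene was marked if at least 1 bp of a replicated peak overlapped it. Neighbouring genes can therefore be marked by the same peak. Coverage is the percent of TSS ± 5 kb in the peaks of each replicate's own list, given as mean ± SD (n = 2). Bases were assigned in the order promoter, exon, intron and intergenic. CpG islands were found in the reference sequence as stretches of at least 200 bp with at least 50% GC and an observed over expected CpG ratio of at least 0.6, which gave 73826 islands. Domains joined replicated peaks across gaps of up to 3 kb. Shuffles, 100 with fixed seeds, kept each peak on its chromosome and did not model mappability.

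The 28 gene lists, their tests and the alternatives were fixed before the data were examined. Each list was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 28 lists and a threshold of 0.05. Odds ratios had 0.5 added to each count. This test treats genes as independent, which neighbouring genes are not, so 10000 circular shifts of the marks along the gene order were run beside it. All symbols matched except that 1 T-box name was an older name of a gene already in the list. Genes named in the text were, per list, up to 3 marked members with the largest coverage and up to 2 unmarked members with the smallest, ties in alphabetical order. Further named genes were those with a TSS in the 10 widest domains, 14 genes of lung development and Polycomb biology, the 10 with the highest signal value at the promoter, and counterexamples to a list's direction that were marked in both replicates or in neither. Alternatives changed the peak list, left out each replicate, raised the peak threshold, changed the promoter window, overlap and TSS, limited genes to those with CpG islands, and changed domain gaps.

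Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1. The functions were tested on simulated data. In 20 pairs of simulated interval sets, 0 differed from bedtools, and 50 of 50 planted CpG islands were found. With marks simulated for the 21728 genes and 200 changed genes, lists of 30 were called in 100 of 100 draws at a 4-fold raised share. They were called in 62 of 100 at a 2-fold raised share, 100 of 100 with no marked member, and 2 of 100 when unchanged. Each call used an unadjusted threshold of 0.05. The simulated marks were independent between genes, so the 2 of 100 does not give the rate of false calls for lists of neighbouring genes.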

Results

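Chromatin immunoprecipitation followed by sequencing was used to map trimethylation of lysine 27 of histone H3 (H3K27me3), the mark that Polycomb repressive complex 2 places on repressed chromatin, in lung of mouse embryos of strain B6NCrl at 15.5 days of development. The samples formed 1 group of 2 biological replicates. Replicate 1 pooled the lungs of 78 embryos and was sequenced as 3 technical replicates, and replicate 2 pooled the lungs of 62 embryos with 2 technical replicates. Both pools held male and female embryos. With 1 group there was no contrast between conditions. The comparisons were those between the replicates, between parts of the genome, and between groups of genes fixed before the data were examined. Read numbers were not among the values analysed, so sequencing depth is unknown and no counting interval is given. A missing peak therefore means that none was called, not that the mark was absent. The authors' peak lists held 91592 peaks covering 46.94 Mb for replicate 1 and 44405 peaks covering 23.56 Mb for replicate 2. Their list of replicated peaks held 30951 peaks covering 31.82 Mb, or 1.243% of the sequenced bases of chromosomes 1 to 19 and X in the mm10 assembly.

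The first question was how far the replicates shared their marked regions, since this sets the error of every other value. The strongest regions were common to both pools: each of the top 1000 peaks of either replicate, ranked by the authors' signal value within its own list, overlapped a peak of the other. Of the top 5000 peaks, 96.52% of those of replicate 1 and 99.68% of those of replicate 2 did so. Over all peaks, 79.87% of the bases of replicate 2 lay in peaks of replicate 1, and 40.1% of the bases of replicate 1 lay in peaks of replicate 2. When the peaks of replicate 2 were shuffled 100 times within their chromosomes, the highest corresponding shares were 2.32% and 1.16%, and in 100 shuffles within 1 Mb they were 7.47% and 3.69%. The highest signal values of the overlapping peaks were correlated across 21971 replicated peaks (Spearman's rho = 0.573), a relation across peaks, which are not independent replicates. All 30951 replicated peaks were identical to peaks the authors called on both replicates together. Peaks of replicate 1 covered at least 50% of the length of 91.0% of them and peaks of replicate 2 of 55.81%, and 260 overlapped neither replicate's own list.

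H3K27me3 lay over the promoters of a minority of genes. A replicated peak overlapped the transcription start site (TSS) ± 1 kb of 3673 of 21728 protein-coding genes (16.9%), hereafter called marked. With each replicate's own peaks the share was 19.32% ± 3.64 (SD, n = 2), from 4756 genes in replicate 1 and 3638 in replicate 2. Of the 3638 genes marked in replicate 2, 94.09% were marked in replicate 1. Replicate 1 alone marked 1333 genes and replicate 2 alone 215, from lists of different length, so these counts compare no condition. The 10 genes with the highest signal value of a replicated promoter peak were Adra2c, Bhlhe23, Hmx1, Nrg3, Egr4, Kcnc1, Prmt8, Cdx2, Wnt3a and Gabbr2. They included receptors and channels of neurons (the adrenergic receptor gene Adra2c, the potassium channel gene Kcnc1 and the GABA-B receptor gene Gabbr2) and the intestinal regulator Cdx2. Signal values of their peaks ran from 12.22 at Gabbr2 to 15.93 at Adra2c (chromosome 5, 35278319 to 35281763). All 10 were marked in both replicates.

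Marked bases were concentrated at promoters and exons. Promoters held 14.77% of the bases in replicated peaks, against 1.6% of the genome, a 9.23-fold difference. In the replicates' own lists the share was 13.35% ± 3.4 (SD, n = 2), and 100 shuffles gave 1.53% to 1.87%. Exons outside promoters held 11.41% of the bases in replicated peaks against 4.53% of the genome. Introns held 40.14% against 41.91%, slightly below the shuffles (40.95% to 43.46%), and the replicates' SD was 1.3 percentage points. Intergenic sequence held 33.68% against 51.95%. Promoters with a CpG island, a stretch rich in the CG dinucleotide, were marked more often than those without. Of 13223 genes with an island, 3037 (23.0%) were marked, against 636 of 8505 (7.48%) without (Fisher's exact test, two-sided, odds ratio 3.69, p = 3.3e-213). Genes are not independent replicates, and this p-value describes genes within 1 tissue.

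Most HOX genes and most listed regulators of neural, pancreas, liver and gut, and heart and muscle development carried the mark. The shares ran from 68.2% of the heart and muscle list to all HOX genes. All 39 HOX genes, which pattern the body axis, were marked in both replicates, and 86.4% ± 7.4 (SD, n = 2) of the sequence within 5 kb of their TSSs lay in peaks. Of 52 regulators of neural patterning and neuronal lineages, 50 were marked. Neurog1, a determinant of neurons, and Olig2, a determinant of oligodendrocytes and motor neurons, were covered over 100% of TSS ± 5 kb in both replicates, and Pax7 over 99.6% ± 0.62. The exceptions were Neurod4, with no peak within 5 kb of its TSS, and Neurod6. The latter had a promoter peak in each replicate's own list but no replicated peak within 1 kb of its TSS. Of 22 regulators of pancreas, liver and gut, 20 were marked, among them Mnx1 (98.9% ± 1.53 covered), Onecut1 (98.8% ± 1.65) and Cdx2 (98.2% ± 2.55), while Hnf4a and Hnf1a had no replicated promoter peak. Hnf4a had a promoter peak in the list of replicate 1 only, and Hnf1a in that of replicate 2 only. Among heart and skeletal muscle regulators 15 of 22 were marked, including Hand2 (96.8% ± 3.16) and Hand1 (96.3% ± 4.02), and Mef2c and Smyd1 had no peak within 5 kb. By Fisher's exact test against all other protein-coding genes, with Benjamini-Hochberg adjustment over the 28 gene lists, the odds ratios were 392.5 for HOX genes (adjusted p = 4.61e-30) and 100.6 for the neural list (adjusted p = 2.47e-35). HOX genes are neighbours that share domains, so Fisher's exact test gives them too small a p-value. Both lists also passed the permutation test by circular shifts along the gene order (adjusted p = 1.87e-04 for each). The odds ratio was 173.1 for the neural list and 71.7 for the pancreas, liver and gut list with the peaks of replicate 2 alone, with 51 of 52 and 21 of 22 members marked. With replicated peaks the odds ratios were 40.5 for the pancreas, liver and gut list (Fisher's exact test, adjusted p = 2.64e-13) and 10.2 for the heart and muscle list (Fisher's exact test, adjusted p = 3.08e-07).

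**Figure D1:**
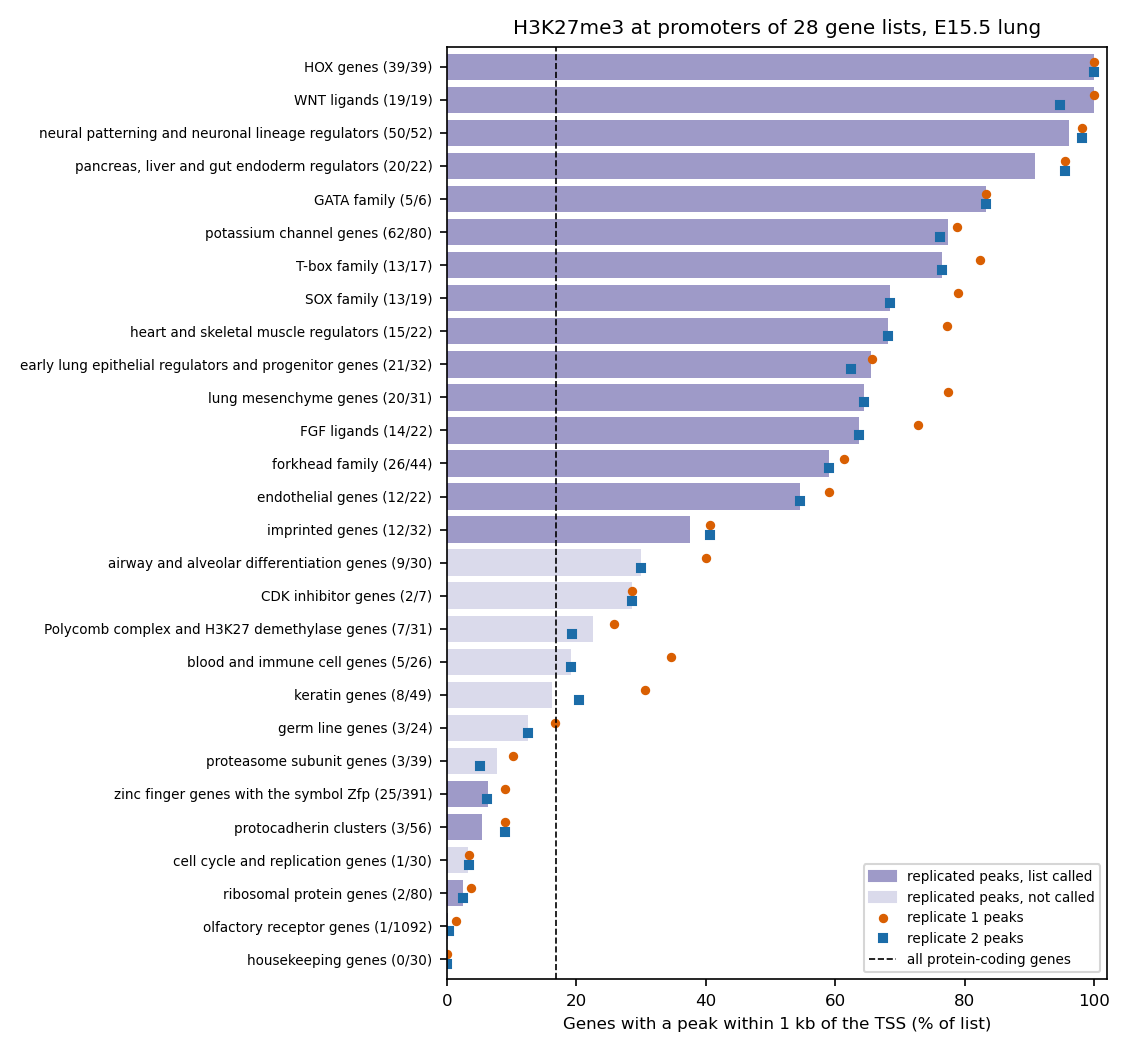
Percent of the genes of each of 28 lists with a peak within 1 kb of the TSS, from replicated peaks (bars, dark where the list passed the test) and from the peaks of replicate 1 (circles) and replicate 2 (squares), with marked and measured members in brackets and the share of all protein-coding genes (16.9%) as a dashed line. The HOX and WNT lists reached 100% and no housekeeping gene was marked.

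Regulators of the lung itself were marked as well. The labels give lung and name no isolated cell type, so a peak does not tell which cells of the lung carried the mark. A marked gene may therefore be one that other cells of the lung use. Of 32 early lung epithelial regulators and progenitor genes, 21 were marked (Fisher's exact test, odds ratio 9.24, adjusted p = 3.44e-09), as were 20 of 31 lung mesenchyme genes (odds ratio 8.80, adjusted p = 1.21e-08). Nkx2-1 (chromosome 12, 56531958 to 56536908), which specifies the lung epithelium, was covered over 85.1% ± 8.46 (SD, n = 2) of TSS ± 5 kb. Foxa2 (chromosome 2, 148042877 to 148046969), a regulator of the foregut endoderm, was covered over 88.6% ± 7.91. Sox2 (chromosome 3, 34650405 to 34652461), a marker of the proximal airway, was covered over 87.7% ± 6.46. Sox9 (chromosome 11, 112782224 to 112787760), a marker of the distal tips, was covered over 40.1% ± 24.5, with weaker peaks: it had no mark at TSS ± 500 bp nor among the replicated peaks with signal values above the median. Shh (chromosome 5, 28456815 to 28467256), a signal from the epithelium to the mesenchyme, was covered over 69.7% ± 3.78. The replicates differed at Bmp4, marked in replicate 1 and in the replicated peaks but not in replicate 2. Elf3 and Ehf, epithelial transcription factors, had no peak within 5 kb in either replicate.

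In the mesenchymal list the marked genes included Wt1 (94.7% ± 3.65 covered, SD, n = 2), a mesothelial regulator, Foxf2 (89.5% ± 13.8), Twist1 (85.3% ± 6.5) and Foxf1 (chromosome 8, 121084386 to 121088144; 77.7% ± 20.4). The limb and lung bud regulators Tbx4 (56.1% ± 21.8) and Tbx5 (49.5% ± 17.3) were marked in both replicates. The fibrillar collagen genes Col1a2 and Col3a1 had no peak within 5 kb. Fgf10 (chromosome 13, 118669791 to 118792115), the mesenchymal signal for branching, was not marked at its 5′ end and was covered over 0.58% ± 0.82, but another annotated TSS of the gene was marked. Among endothelial genes 12 of 22 were marked (Fisher's exact test, odds ratio 5.87, adjusted p = 1.20e-04). These were led by the transcription factor genes Gata2 (99.3% ± 1.0), Sox7 (91.5% ± 5.81) and Tal1 (90.6% ± 11.7), while Cdh5, which encodes an endothelial junction protein, and Egfl7 had no peak within 5 kb. All 12 marked endothelial genes were among the 14 with a CpG island at the promoter.

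**Figure D2:**
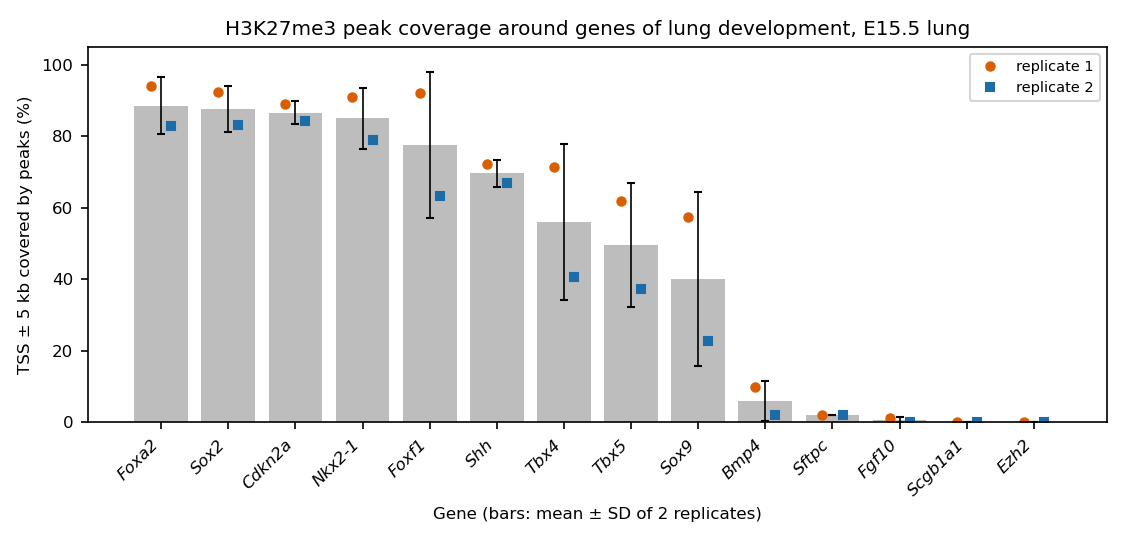
Percent of TSS ± 5 kb covered by peaks at 14 genes chosen before the data were examined, as the mean of both replicates (bars) ± SD (lines, n = 2), with the values of replicate 1 (circles) and replicate 2 (squares). Foxa2, Sox2, Cdkn2a and Nkx2-1 lay above 80% on average, and Ezh2 and Scgb1a1 had no peak in the window.

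Genes of differentiated airway and alveolar cells did not pass the test as a list: 9 of 30 were marked (Fisher's exact test, odds ratio 2.17, adjusted p = 0.104). The marked members were led by Aqp5 (99.4% ± 0.88 covered, SD, n = 2), a water channel of alveolar type 1 and gland cells, Mcidas (91.6% ± 3.33), which starts multiciliated cell differentiation, and Ascl1 (88.9% ± 3.41), a determinant of neuroendocrine cells. Sftpc (chromosome 14, 70520949 to 70524081), which encodes a surfactant protein, and Scgb1a1, a club cell gene, were unmarked in both replicates, as were Ager and Cyp2f2. All 9 marked genes were among the 13 members with a CpG island. Within genes with an island the list did pass the test (Fisher's exact test, odds ratio 7.10, adjusted p = 8.79e-04). It also passed with the peaks of replicate 1 alone (Fisher's exact test, adjusted p = 0.0317) and under other settings given in the closing section.

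The WNT, FGF, T-box, SOX, GATA, forkhead and potassium channel families were marked above the genome-wide share. Some lists share members. Sox2, Sox9, Foxa2, Foxf1, Tbx4 and Tbx5 also belong to the lung lists, Sox7 and Gata2 to the endothelial list and Tbx20 to the heart and muscle list. The calls of these families are therefore not independent of those lists. All 19 WNT ligand genes were marked (Fisher's exact test, odds ratio 192.7, adjusted p = 1.16e-14), including Wnt10a (99.0% ± 1.48 covered, SD, n = 2), Wnt10b and Wnt3a. With the peaks of replicate 2 alone 18 of 19 were marked, at an odds ratio of 61.6. Of 22 FGF ligand genes 14 were marked (Fisher's exact test, odds ratio 8.41, adjusted p = 2.49e-06), led by Fgf8 (85.5% ± 1.79) and Fgf3 (77.2% ± 8.82), while Fgf1 and Fgf20 had no peak within 5 kb. The T-box family had 13 of 17 members marked, led by Tbx20 and Tbx15 (odds ratio 14.8), the SOX family 13 of 19, led by Sox1 (97.0% ± 0.85) and Sox14 (odds ratio 10.2), and the GATA family 5 of 6, with Gata1 unmarked (odds ratio 18.1). Of 44 forkhead genes 26 were marked, led by Foxb2 (98.2% ± 1.69), Foxb1 and Foxe1, while Foxj2 and Foxj3 had no peak within 5 kb (odds ratio 7.08). The adjusted p-values of these families by Fisher's exact test were 2.78e-07 for T-box, 1.91e-06 for SOX, 0.00117 for GATA and 1.36e-09 for forkhead genes. Potassium channel genes, which set membrane potential in neurons and muscle, had 62 of 80 members marked (Fisher's exact test, odds ratio 16.9, adjusted p = 1.17e-31), among them Kcnh3 (91.9% ± 10.4), Kcnc4 (91.0% ± 3.68) and Kcnj4 (89.8% ± 4.88).

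Housekeeping, ribosomal protein, Zfp, olfactory receptor and clustered protocadherin genes were marked below the genome-wide share. None of 30 housekeeping genes, Actb and B2m among them, had a replicated promoter peak (Fisher's exact test, odds ratio 0.08, adjusted p = 0.00955), although the call ended when at least 50% of the promoter had to be covered (Fisher's exact test, odds ratio 0.137, adjusted p = 0.0879). Under that rule the list still had no marked member, while marked genes overall fell from 3673 to 2321. Of 80 ribosomal protein genes 2 were marked (Fisher's exact test, odds ratio 0.156, adjusted p = 2.15e-04): Rpl3, whose TSS lies 534 bp from that of the marked gene Syngr1, and Rpl3l, a muscle paralog marked in replicate 1 only. Of 391 zinc finger genes with the symbol Zfp 25 were marked (Fisher's exact test, odds ratio 0.337, adjusted p = 2.92e-09). They included Zfp536 (73.7% ± 19.4 covered, SD, n = 2) and Zfp853 (63.5% ± 2.79). Olfactory receptor genes had 1 of 1092 members marked, Olfr95, with a promoter peak in replicate 1 but not in replicate 2 (Fisher's exact test, odds ratio 0.006, adjusted p = 5.73e-87). The peaks of replicate 1 alone marked 15 of them (odds ratio 0.048) and those of replicate 2 alone 4 (odds ratio 0.019). Only 9 of them have a promoter CpG island, and among genes with an island the list did not pass (Fisher's exact test, adjusted p = 0.263). Of 56 clustered protocadherin genes 3 were marked (Fisher's exact test, odds ratio 0.321, adjusted p = 0.0264), led by Pcdhac2 (35.7% ± 8.57). These genes lie side by side, and the call was lost when marks were shifted along the gene order (permutation test by circular shifts, adjusted p = 0.26). It was also lost with the peaks of replicate 2 alone (Fisher's exact test, adjusted p = 0.182).

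Imprinted genes, expressed from 1 parental copy, were marked in 12 of 32 cases (Fisher's exact test, odds ratio 3.00, adjusted p = 0.0102), with Dio3 (91.3% ± 5.18 covered, SD, n = 2), Rasgrf1 (84.2% ± 15.9) and Grb10 (73.8% ± 18.5) the most covered and Ddc and Igf2r without a peak within 5 kb. With the peaks called on both replicates together the call was lost (Fisher's exact test, adjusted p = 0.0682). The remaining lists did not pass Fisher's exact test. Of 7 CDK inhibitor genes the neighbours Cdkn2a (chromosome 4, 89274471 to 89294653; 86.7% ± 3.32) and Cdkn2b (64.6% ± 20.9) were marked, and Cdkn1b and Cdkn2d had no peak within 5 kb (Fisher's exact test, odds ratio 2.23, adjusted p = 0.393). Of 31 Polycomb and H3K27 demethylase genes 7 were marked, led by Cbx8 (71.7% ± 7.19) and Epop (67.9% ± 6.0), while the methyltransferase gene Ezh2 and Eed had no peak within 5 kb (Fisher's exact test, adjusted p = 0.525). Blood and immune genes had 5 of 26 marked, led by Gata3, Ebf1 and Tbx21 (Fisher's exact test, adjusted p = 0.822), and keratin genes 8 of 49, led by Krt8 (adjusted p = 1). With the peaks of replicate 1 alone these lists had 9 and 15 marked members (odds ratios 1.939 and 1.605). Germ line genes had 3 of 24 marked (Tdrd1, Sycp2 and Dmc1, each under 10% covered; Fisher's exact test, adjusted p = 0.822). Proteasome genes had 3 of 39, including the immunoproteasome genes Psmb8 and Psmb9 (Fisher's exact test, adjusted p = 0.169). Cell cycle and replication genes had 1 of 30, Pole, whose TSS lies 120 bp from that of Pxmp2 (Fisher's exact test, odds ratio 0.25, adjusted p = 0.0653). With the peaks of replicate 1 alone the cell cycle list passed (Fisher's exact test, adjusted p = 0.0186).

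The broadest domains lay over the HOX clusters. Replicated peaks joined across gaps of up to 3 kb formed 11806 domains, of which 920 were at least 10 kb wide and 31 at least 50 kb. Peaks of replicate 1 alone formed 31023 domains, those of replicate 2 alone 17413, and pooled peaks 25693. Those at least 10 kb wide numbered 2073, 808 and 1966, and those at least 50 kb wide 91, 23 and 89. With replicated peaks joined across 10 kb, 1694 and 138 domains reached these widths, and across 1 kb, 577 and 11. The widest, on chromosome 15 from 102889307 to 103109057 (219.8 kb), held the 9 HoxC genes, and 83.3% ± 8.2 (SD, n = 2) of it lay in peaks of the replicates' own lists. HoxA with Evx1 followed on chromosome 6 from 52140214 to 52325874 (185.7 kb, 74.8% ± 13.8), and HoxD with Evx2 on chromosome 2 from 74642232 to 74772966 (130.7 kb, 92.3% ± 3.8). Hoxb2 to Hoxb9 lay in a domain on chromosome 11 from 96230262 to 96354981 (124.7 kb, 70.7% ± 15.9), and Hoxb13 in a separate one of 80.4 kb. Domains among the 10 widest also held Pax7 (105.1 kb) and Pax3 (89.8 kb), regulators of muscle precursors and neural crest, and the ephrin receptor gene Epha8 (78.4 kb). The domain at Iqsec2 on chromosome X (113.9 kb, from 152112253 to 152226197) differed most between the replicates, with 58.0% of it in peaks of replicate 1 and 20.7% in peaks of replicate 2. A domain of 78.5 kb on chromosome 9, from 61270195 to 61348729, held no protein-coding TSS and overlapped the long noncoding RNA gene B930092H01Rik.

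**Figure D3:**
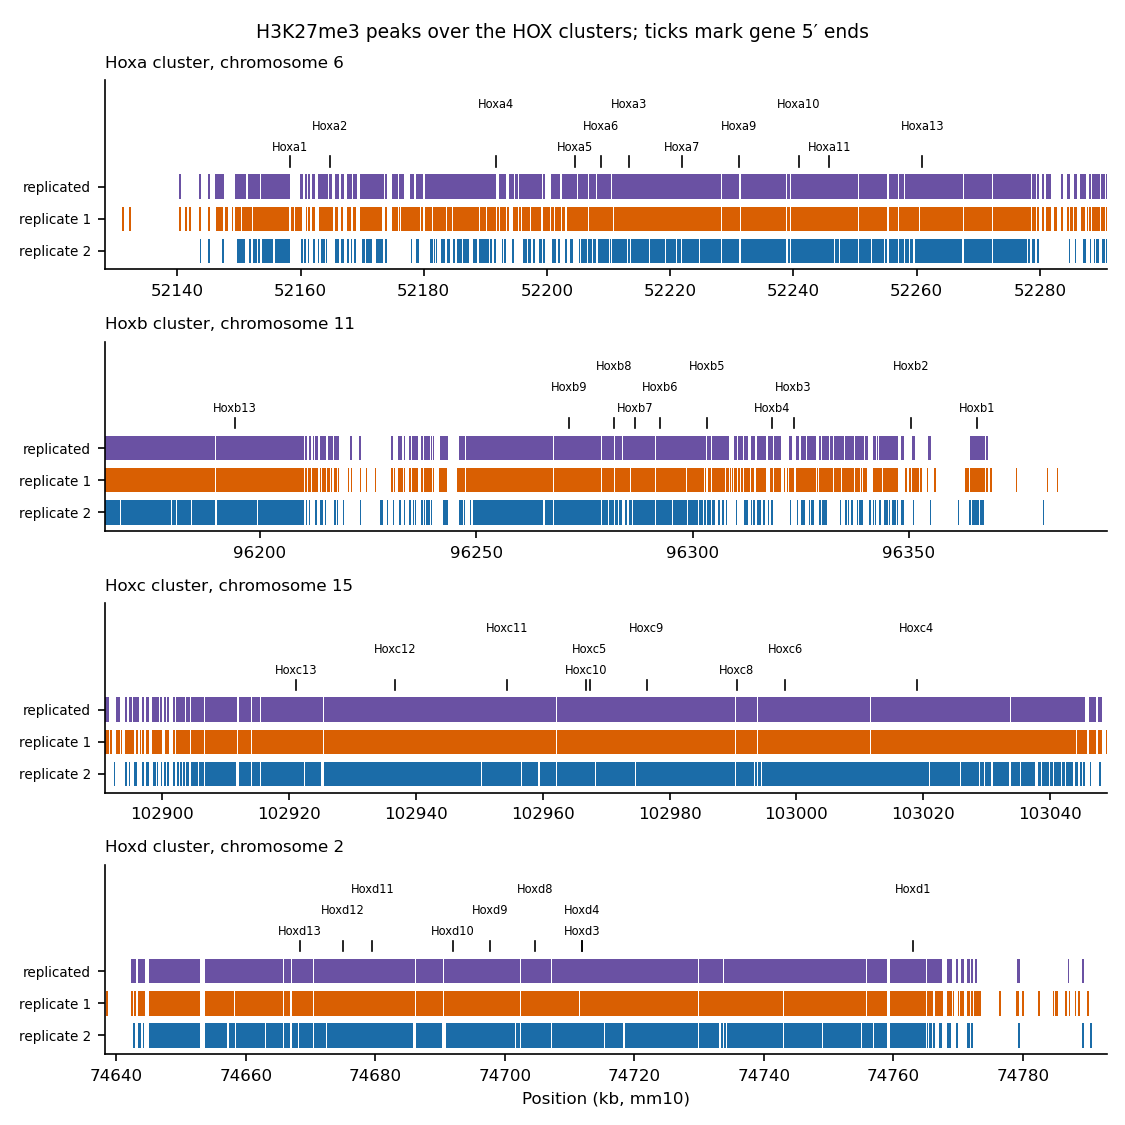
Replicated peaks (top row of each panel) and the peaks of replicate 1 and replicate 2 over the 4 HOX clusters, drawn to scale against position in kb (mm10), with ticks at the annotated 5′ ends of the HOX genes. Peaks covered the HoxC and HoxD clusters nearly without gaps, and coverage was less complete around Hoxa1, Hoxa2, Hoxa4 and Hoxb1 to Hoxb4 in both replicates.

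Chromosome X separated the replicates. Replicate 1's peaks covered 2.812% of X, 1.54 times the median autosome (1.828%), whereas those of replicate 2 covered 0.53%, or 0.54 times the median autosome (0.98%). Among the 20 chromosomes X ranked 3 in replicate 1 and 19 in replicate 2. Replicated peaks covered 1.061% of X, 0.81 times the median autosome and rank 11, whereas pooled peaks gave 1.24 times and replicated peaks outside TSS ± 5 kb 1.29 times. At promoters, 29.11% of X-linked genes were marked in replicate 1 and 12.97% in replicate 2, while autosomal genes were at 21.56% and 16.92%. Of the bases of replicate 1 on X, 11.33% lay in peaks of replicate 2, compared with 43.22% on the autosomes. With 1 such chromosome and 2 replicates no test of this difference across samples was possible, and the mean for X, 1.671% ± 1.614 (SD, n = 2), has an error as large as itself.

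**Figure D4:**
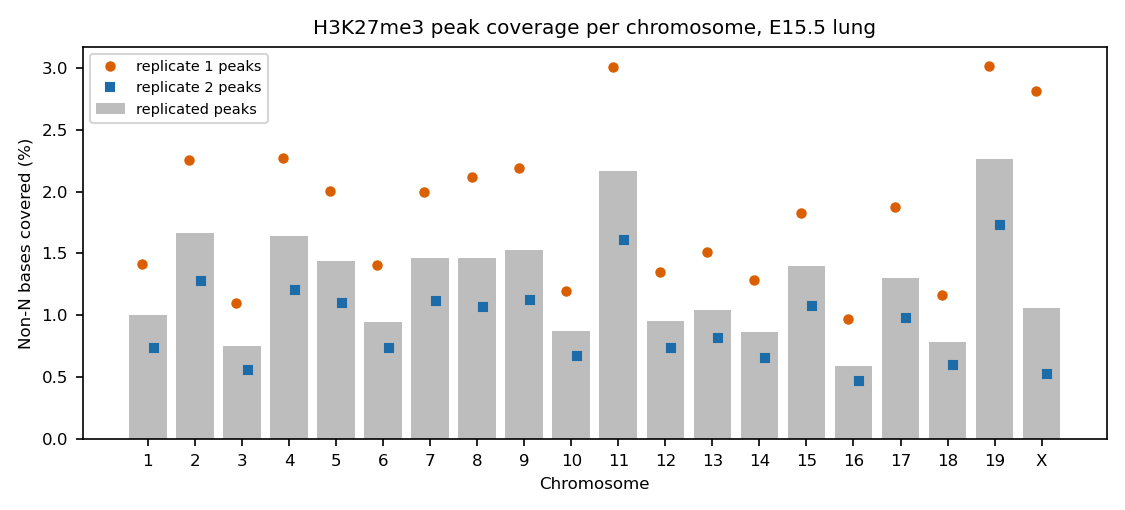
Percent of the sequenced bases of each chromosome covered by replicated peaks (bars) and by the peaks of replicate 1 (circles) and replicate 2 (squares). Replicate 1 lay above replicate 2 on every chromosome, with the widest gap on X (2.812% against 0.53%).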

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

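The alternatives in this part were all fixed before the data were examined. Of 36 results, 21 were counted as the same under every alternative run. Among them, CpG island promoters and these lists kept their direction and side of the threshold: HOX, neural, WNT, potassium channel, early lung epithelial, lung mesenchyme and endothelial. For the results not among the 21 the cause was not tested. Over 374 values, 335 were counted as the same, 16 newly passed a threshold, 8 no longer did, 5 moved and 10 turned direction. Shares and counts without a test, such as replicate overlap and domain number, have no threshold, and sizeable changes in them could count as the same. The change from 11806 domains to 17413 without replicate 1 was counted so. These totals therefore do not show that such values were stable. Promoter marking fell to 2321 genes when at least 50% of the promoter had to be covered. The promoter share of bases ranged from 10.95% to 15.75% with 1 replicate left out and was 32.05% with TSS ± 2.5 kb, a wider window by construction. Coverage of X over the median autosome ranged from 0.54 to 1.54 with 1 replicate left out, and was 1.24 with pooled peaks and 1.29 outside TSS ± 5 kb. Domains numbered 25693 with pooled peaks and 17413 to 31023 with 1 replicate left out.

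The odds ratios that changed side or direction were as follows. With pooled peaks they were 0.186 for cell cycle genes, now past the threshold, and 2.233 for imprinted and 0.553 for protocadherin genes, no longer past it. With 1 replicate left out, cell cycle genes ranged from 0.181 to 0.252, protocadherins from 0.38 to 0.53 and airway and alveolar genes from 2.2 to 2.415; without replicate 2 the first and last passed, and without replicate 1 protocadherins did not. The airway and alveolar list passed with bases in both replicates' lists (2.513), peaks above the median signal (2.772), TSS ± 500 bp (2.541), promoters covered to at least 50% (3.166), any annotated TSS (3.25) and CpG island genes (7.098). Cell cycle genes also passed with peaks above the median signal (0.102), any TSS (0.213) and CpG island genes (0.17). CDK inhibitors passed with TSS ± 2.5 kb (5.178) and any TSS (5.409). Among CpG island genes blood and immune (5.277) and proteasome genes (0.257) passed, and protocadherin (0.35) and olfactory receptor genes (0.176) did not. Protocadherins also missed it with TSS ± 500 bp (0.375) and circular shifts (0.321), and housekeeping genes with promoters covered to at least 50% (0.137). Keratin genes, never past the threshold, turned below 1 with bases in both lists (0.561), peaks above the median signal (0.773), a −log10 p of at least 5 (0.769), TSS ± 500 bp (0.857) and promoters covered to at least 50% (0.629), and Polycomb genes with TSS ± 500 bp (0.939) and promoters covered to at least 50% (0.411). No paired analysis was possible because the samples form 1 group. Depth is unknown, so an unmarked promoter may lie under the detection limit of a library.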

Other observations

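Annotated 5′ ends outside protein-coding genes also carried the mark. Of 4678 long intergenic noncoding RNA genes more than 5 kb from a coding TSS, 303 (6.48%) were marked, and with the replicates' own peaks 9.98% ± 3.69 (SD, n = 2). The shares were 8.09% of 1891 antisense genes, 5.36% of 1771 microRNA genes and 1.68% of 9152 processed pseudogenes at that distance, and with the replicates' own peaks 10.87% ± 2.95, 6.86% ± 2.2 and 3.04% ± 1.61 (SD, n = 2). Without the limit on distance they were 8.39% of 5305 long intergenic noncoding RNA genes, 14.1% of 2958 antisense genes, 6.69% of 2196 microRNA genes and 2.05% of 9849 processed pseudogenes, against 16.89% of protein-coding gene records. In the same order, the replicates' own peaks gave 11.84% ± 3.79, 16.58% ± 3.13, 8.58% ± 2.35 and 3.58% ± 1.87, against 19.3% ± 3.64 (SD, n = 2). The domain of HoxC included the noncoding RNA gene Hotair, a gene chosen after its values were seen. These classes were not compared by a test, nor with windows at random positions. A low share, such as the 1.68% of processed pseudogenes, may therefore be no more than background.

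In what follows the test with matched autosomal bases, the strong promoter peaks on X and the HOX window at the start codon were chosen after the data were seen. The bounds of the other tests were written before their results.

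Within the HOX clusters, coverage rose with paralog group. Groups 9 to 13 (16 genes) had 97.0% ± 1.9 (SD, n = 2) of TSS ± 5 kb in peaks and groups 1 to 5 (15 genes) 71.8% ± 13.4, a difference of 25.3 percentage points (permutation test across genes, two-sided, p = 4e-05), and 28.2 points in windows around the start codon. HOX genes are neighbours, not independent replicates, so this p-value is too small, although the order held in both replicates (98.4% against 81.2%, and 95.7% against 62.3%). It rested on HoxA (95.5% against 69.1%) and HoxB (97.7% against 51.7%), since HoxC had 97.7% against 98.6% (97.7% against 96.3% around the start codon) and HoxD 97.3% against 91.8%. Position along the body axis stays open as an explanation, since the difference of 25.3 points is the pattern itself and no independent test of it was made.

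Promoters marked in replicate 1 only had weaker peaks. Their median highest signal value in replicate 1 was 2.74, against 4.79 at promoters marked in both, a ratio of 0.57. Promoters marked in replicate 2 only were weaker as well (2.55 in replicate 2, against 3.73 at promoters marked in both), so the lower values alone do not single out replicate 2. Lower sensitivity of replicate 2 at weak peaks could account for the 0.57 but is not the only reading, and no biological explanation was tested. It does not cover X evenly: 160 of the 1333 promoters marked in replicate 1 only were on X, compared with 4.36% of all genes and 3.39% of those marked in both.

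Cutting replicate 1 to the peak number of replicate 2 left an excess of peaks on X. With both replicates at 44405 peaks, 13.22% of peaks in replicate 1 and 6.46% in replicate 2 lay on X, a ratio of 2.05. Equal peak numbers did not make the lists equal, since replicate 1 still covered more bases in most bins of each autosome. Uncut, replicate 1 covered 2.812% of X and replicate 2 0.53%. Cut to the autosomal bases of replicate 2, replicate 1 covered 1.27 times the bases of replicate 2 on X. That cut kept the 18435 strongest peaks of replicate 1, set against all 44405 of replicate 2. Peaks on X were rare among the strongest, at 0.3% of the top 1000 of replicate 1. Such a cut takes out X peaks whatever the cause, so the 1.27 does not show how much went with the longer list. At equal list lengths the share on X stayed higher in replicate 1, with 5.69% against 2.73% of the top 10000 peaks. It was 14.29% against 6.8% of the top 40000, so list length alone does not account for it. A factor common to all X fragments, such as the proportion of female embryos or the control libraries, cannot be told apart from a local one. The log2 ratio of signal values between replicates differed by −0.054 between X and autosomes at promoter peaks (bootstrap interval −0.116 to −0.001) and by −0.076 at other peaks, but only peaks seen in both replicates enter, which leaves out most of the excess on X, and the signal scale is not stated, so the values decide nothing; the 49 X promoter peaks with signal values at or above the median of promoter peaks gave −0.04 (−0.096 to 0.064). Mark spread along the inactive X also stays open: replicate 1 covered more bases in 94.7% of 1 Mb bins of X, past the bound of 75% set beforehand, but so did each autosome (77.9% to 90.9%), so the test could not discriminate, and with autosomal bases matched in 60.9% of X bins against 31.9% to 47.3% on the autosomes; the sex ratio of the pools is not given.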
